A study of Mus musculus with 6 samples.

How the data were processed

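The series holds 6 RNA-seq libraries of auditory nerve from CBA/CaJ mice, 3 young (2 months) and 3 old (2.5 years). Per the labels' protocols, the nerve was microdissected out of the cochlea, the tissue of both cochleas of a mouse was pooled into 1 sample, total RNA was purified with a miRNeasy kit, samples with degraded or contaminated RNA were excluded after a Bioanalyzer run, and libraries were made with a TruSeq RNA kit. Whether the kit marked strand is not given in the sources used here, so overlapping and antisense genes cannot be separated by strand. Per the submitters' processing notes, the build was mm10 and the tools were TopHat2, Partek and DESeq2. Their versions, order and settings, the annotation and the read filters are not given in the sources used here.

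The deposited table has 17607 genes with their mm10 positions. Its 6 sample columns are a signal that the authors made by dividing each gene's read count by 1 size factor per library (DESeq2 normalised counts), as the values as deposited show. Each column is made of whole multiples of the value of 1 read, which was 0.940, 0.983 and 1.10 in young 1, 2 and 3 and 1.06, 0.949 and 0.967 in old 1, 2 and 3. Dividing by it gave whole reads within a tolerance of 0.1 for 99.931% to 99.971% of the values above 0. The deposited p-values and the FDR column are the authors' own, per the file headers, from their comparison of old with young. The deposited fold change, a signed score per the file headers, is old over young, with a fall written as the negative inverse. The lowest row total in the table is 9.41, and genes below that were not analysed here. Start positions count from 1, and the end printed is the deposited stop less 1.

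The test planned before the data were examined was edgeR's quasi-likelihood test on counts. The table turned out to hold normalised values, so the fallback written in the same plan became the main test. It is limma (3.58.1) with trended empirical Bayes variances on log2(value + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes entered the fit if edgeR's filterByExpr kept their recovered reads (minimum count 10, minimum total 15), which left 15882. On the recovered reads edgeR (4.0.16) called 5401 genes (2547 higher, 2854 lower), 5316 of them shared with limma. The authors' deposited table has 6128 genes with an FDR under 0.05 (2892 higher, 3236 lower), 5464 of them shared with limma. With 3 mice against 3, an exact permutation test of a single gene cannot go below p = 0.1, so the p-values rest on limma's model. Depth was similar in all libraries, and the 10 most abundant genes took 4.69% to 7.39% of reads. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 18.9 to 66.2), so none is a repeat of another library.

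Named genes follow a rule set before the data were examined. Among genes with an adjusted p under 0.05, at least a 2-fold change, a mean at or above the median of tested genes (926) and complete separation of the groups, the 12 largest rises and the 12 largest falls were taken. There were 261 such genes (95 higher, 166 lower), and 2 without an approved name were left out. Up to 4 members of each gene list with the smallest p were named too. Some genes that the rule takes are not reported here. Other list members are named as counterexamples or because a few genes make up a count, and they were chosen after their values were seen. The 45 lists, of marker genes and of functions, were fixed before the data were examined, and 40 had at least 5 tested genes. They were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over lists. Repeats used a correlation estimated from the data and limma's fry. Fry tests whether the genes of a list move on balance one way, without comparing them with other genes. Of the listed genes, 28 stand in several lists.

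Transcript length and GC content came from the longest protein-coding transcript of each gene in GENCODE release M21 (GRCm38), matched by symbol for 98.6% of tested genes. To remove their trends, a smooth curve in each (mgcv 1.9.3) was fitted per library to the deviations from the gene means and subtracted. This alternative, edgeR with TMM scaling, TMM scaling within limma, the fit without young 1 and old 2, the authors' own FDR and fry were added after seeing the data. The alternatives set beforehand were DESeq2 (1.42.0), other scalings, filters, pseudocounts and thresholds, the replicate number as a block, and each library left out in turn. The plan also held list tests without the genes that stand in several lists. A sign change between values that both miss the threshold was counted as no change of call.

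The steps were tested on simulated counts with the real means, library sizes and 200 changed genes. Over 15882 genes limma recovered 25.4% of genes changed 1.5-fold, 65.7% at 2-fold and 83.3% at 4-fold, with 15 false calls among 131. That share of false calls is above the 0.05 that the threshold aims at. Far fewer genes were changed than the 5493 called in the data. The adjustment was therefore stricter in the simulation, and these rates are not the sensitivity of the real comparison. Without any change limma called 0 genes and 0 of 40 lists. The simulated genes varied independently of each other, so this does not test the list calls where genes move together. With a trend in length added, 413 false calls were made, and 16 after the removal described above. Of the changed genes with a mean below the median 36 of 103 were recovered, and 80 of 97 of the others. Smaller changes and changes of genes with few reads can therefore be missed. A gene listed at 0 in a group can only be bounded, with a floor of 3 reads over the group. Reads do not carry molecular identifiers in the sources used here, so such bounds cover counting error only. Counting tools can split reads between near-identical genes, such as the H2, C4a and C4b, metallothionein and hemoglobin genes, and their values are uncertain to that extent. Mitochondrially encoded genes were not analysed here. R 4.3.3 was used throughout.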

Results

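The auditory nerve carries signals from the sensory hair cells of the cochlea to the brainstem and holds the spiral ganglion neurons with their Schwann cells and satellite glia. Gene expression was measured by RNA sequencing in nerves microdissected from CBA/CaJ mice, an inbred strain used in hearing research. There were 3 young mice aged 2 months and 3 old mice aged 2.5 years. Each library came from the pooled cochleas of 1 mouse, so the replicates are separate animals. The recovered reads per library came to 40841478, 39973113 and 35213213 in young 1, 2 and 3 and to 34587978, 38486427 and 38835751 in old 1, 2 and 3. Values below are normalised read counts as mean ± SD with n = 3 per group. Log2 fold changes are old minus young on the log2(value + 1) scale with their SE. The added 1 shrinks the change of genes with few reads, but their values can also exceed edgeR's, as in Jchain (3.53 against 2.96). Adjusted p-values come from limma.

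The comparison asked which transcripts differ in the nerve between young adulthood and old age. Of 40 gene lists fixed beforehand 19 passed the list test, 13 up and 6 down, and none did with an estimated correlation (smallest adjusted p = 0.597). Those that passed included macrophage, complement and MHC class I genes, higher in old nerves, and axonal excitability, synaptic vesicle and osteoblast genes, lower in old nerves. Crhbp, which encodes the binding protein of corticotropin-releasing hormone, rose 5.92-fold, from 4444 ± 1829 to 26289 ± 8325 (log2 fold change 2.61 ± 0.37, adjusted p = 0.00547). Map1a, a microtubule-associated protein, fell from 126035 ± 9872 to 42117 ± 15176 (log2 fold change -1.64 ± 0.25, adjusted p = 0.00611). Of 15882 genes tested, 5493 passed an adjusted p under 0.05, 2524 higher and 2969 lower in old nerves, and 948 of them changed at least 2-fold (577 higher, 371 lower). All 3 old libraries lay on one side of all 3 young libraries in 8222 tested genes, or 51.8%, where chance gives 10%. The count fell to 3565 without young 1, to 2589 without young 2 and to 3077 without young 3, and the 4 libraries other than young 1 and old 2 gave 1776. With upper-quartile scaling 60.3% of calls were rises (3462 higher, 2281 lower), against 46.0% here.

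Log2 fold changes varied with transcript length across tested genes. The correlation across genes between transcript length and log2 fold change was -0.377 (Spearman, 15654 genes, which are not independent replicates), and that with GC content was -0.171. Within libraries, the correlation of length with the deviation from each gene's mean was positive in young 1, 2 and 3 (0.295, 0.376 and 0.266) and negative in old 1, 2 and 3 (-0.276, -0.340 and -0.291). The tenth of genes with the shortest transcripts (median 982 nt) had a median log2 fold change of 0.31, and the tenth with the longest (median 8220 nt) had -0.28. With smooth trends in length and GC removed from each library, a step chosen after seeing the data, 3505 genes passed.

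**Figure D1:**
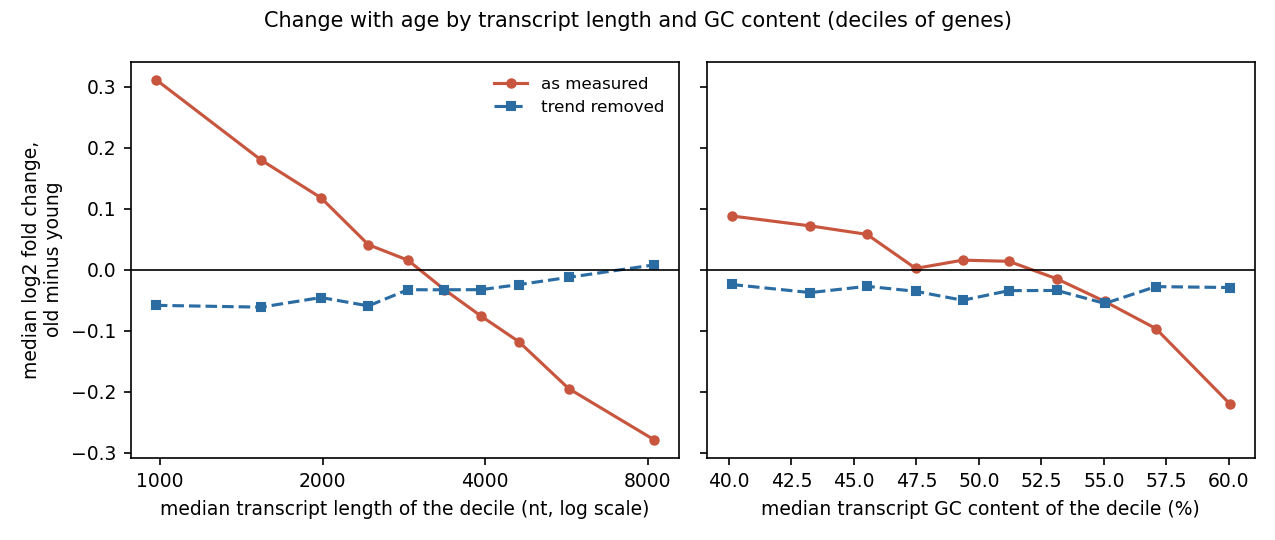
Median log2 fold change (old minus young) of tested genes in deciles of transcript length (left, in nt on a log scale) and of transcript GC content (right, in percent). Circles show the values as measured, which run from 0.31 in the shortest to -0.28 in the longest transcripts, and squares show them with the trends removed.

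Among the 12 named rises, Vmo1 rose from 1671 ± 730 to 9521 ± 2343 (log2 fold change 2.60 ± 0.37, adjusted p = 0.00552). Cndp1, a dipeptidase that cleaves carnosine, rose by a log2 fold change of 2.47 ± 0.42. Lrp2 (megalin), an endocytic receptor of absorptive epithelia, went from 3456 ± 1765 to 14943 ± 4496 (2.23 ± 0.44, adjusted p = 0.0104). Ttr, the thyroid hormone carrier transthyretin, rose by 2.23 ± 0.22 and Scnn1a, the alpha subunit of the epithelial sodium channel, by 2.23 ± 0.34. Postn (periostin), a matrix protein, rose by 2.16 ± 0.24. The other 6 were the complement genes C3 (2.38 ± 0.44), C1qa (2.16 ± 0.17) and C1qc (2.08 ± 0.19), the macrophage genes Mpeg1 (2.29 ± 0.23) and Ctss (2.09 ± 0.18), and Crhbp. In the mm10 build Crhbp lies on chromosome 13 from 95431376 to 95444831, Lrp2 on chromosome 2 from 69424335 to 69586067 and Mpeg1 on chromosome 19 from 12460779 to 12465285.

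The largest named fall was that of Col1a1, a type I collagen chain, from 1995 ± 915 to 364 ± 403 (log2 fold change -2.94 ± 0.73, adjusted p = 0.0208). It stood at 141, 829 and 121 in old 1, 2 and 3. Its adjusted p was 0.0505 with edgeR's quasi-likelihood test and 0.0613, 0.0620 and 0.0670 in limma without young 1, young 3 and old 1. Col15a1 (-1.97 ± 0.12), Col1a2 (-1.65 ± 0.22) and the cartilage genes Col2a1 (-1.84 ± 0.20) and Acan, which encodes aggrecan (-1.59 ± 0.20), fell as well. Ccnd2 (cyclin D2), which drives entry into the cell cycle, fell from 1577 ± 54.4 to 463 ± 126. Other large falls were of genes at work in neurons. Among them were Sv2c, a synaptic vesicle protein (-1.74 ± 0.28), Bsn (bassoon), a scaffold of the presynaptic active zone (-1.67 ± 0.21), Nos1, neuronal nitric oxide synthase (-1.64 ± 0.23), Map1a and Ttbk1, a kinase of tau (-1.63 ± 0.22). With the length and GC trends removed these falls were smaller and still passed, as in Bsn (-0.89, adjusted p = 0.0115). Col15a1 lies on chromosome 4 from 47208012 to 47313165 and Col2a1 on chromosome 15 from 97975602 to 98004724.

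**Figure D2:**
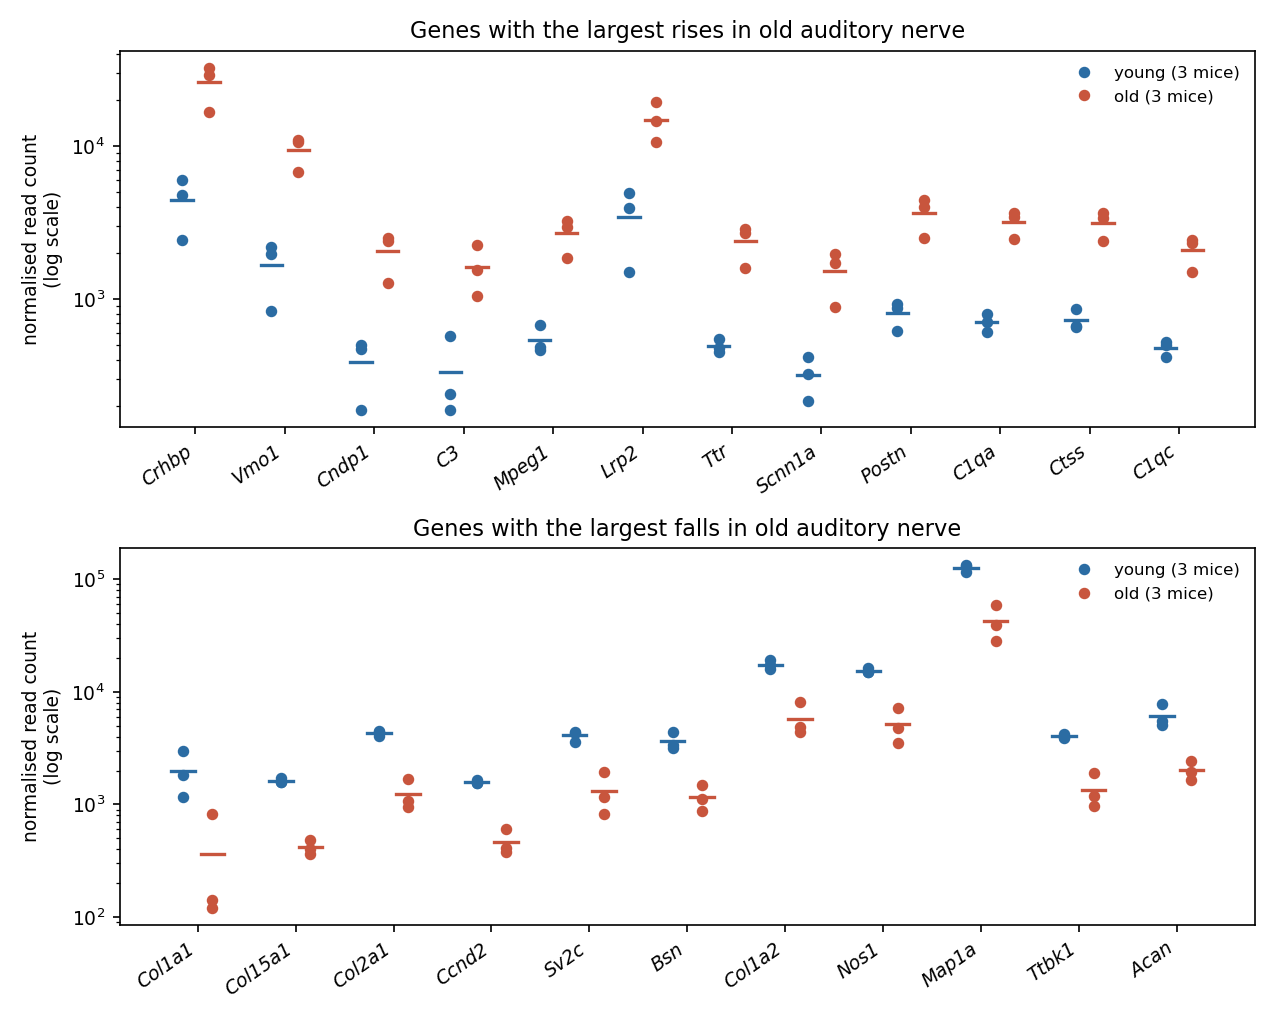
Normalised read counts (log scale) of the 12 genes with the largest rises (upper panel) and 11 of the 12 with the largest falls (lower panel) in each of 3 young and 3 old mice. Points are single mice and bars are group means. In each gene all old mice lie on one side of all young mice, as in Crhbp with means of 4444 and 26289.

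Macrophage and microglia genes rose as a group. Of 25 tested, 22 rose and none fell (also 22 adjusted over the list alone), with a median log2 fold change of 1.26 (camera, adjusted p = 1.05e-10; adjusted p = 0.597 with an estimated correlation). Trem2, a lipid-sensing receptor of microglia and macrophages, rose from 143 ± 31.6 to 699 ± 125, and Cd68, a lysosomal protein of phagocytes, from 223 ± 40.2 to 1035 ± 243. The 3 that did not pass were Tmem119 (0.11), Cx3cr1 (0.35) and Mrc1 (0.35). Of 18 complement genes 11 rose and none fell (12 adjusted over the list alone; median 1.20, camera adjusted p = 7.17e-06; adjusted p = 0.597 with an estimated correlation). C1qb, a chain of the initiator C1q, rose by 2.00 ± 0.17 and C4b by 1.61 ± 0.11, although C4b shares sequence with C4a, so reads could be split between them.

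Genes of MHC class I presentation rose in 13 of 16 cases with no fall (14 adjusted over the list alone; median 1.04, camera adjusted p = 1.05e-06; adjusted p = 0.597 with an estimated correlation). The class I heavy chains H2-K1 (902 ± 62.1 to 2557 ± 460) and H2-D1 (log2 fold change 1.11 ± 0.16), which have close paralogs, and the immunoproteasome subunit Psmb8 (1.51 ± 0.19) were among them. The count was 8 without young 2, 8 without young 3 and 5 without both young 1 and old 2. Of 9 class II genes 3 rose (6 adjusted over the list alone; median 1.17, camera adjusted p = 0.0220; adjusted p = 0.597 with an estimated correlation). The 3 were H2-DMb1 (1.31 ± 0.28), H2-Aa (1.47 ± 0.43) and H2-DMb2 (1.11 ± 0.34), at means of 113, 221 and 62.3 in old nerves. Of them 1 passed with the length and GC trends removed (H2-Aa had an adjusted p of 0.102 and H2-DMb2 one of 0.106). The count of rises was 1 without young 3, 1 without old 2, where the list did not pass (adjusted p = 0.0735), and 0 without young 2.

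Interferon response genes had a median log2 fold change of 1.22 over 29 genes, of which 3 passed as rises (3 adjusted over the list alone; camera adjusted p = 1.08e-04; adjusted p = 0.641 with an estimated correlation). The 3 were Oas1a (2.17 ± 0.51), Ifi35 (0.84 ± 0.21; with the trends removed 0.58, adjusted p = 0.0701) and Ifit2 (1.19 ± 0.29). The old libraries differed widely, as in Ifit3, with 12533, 3854 and 1838 in old 1, 2 and 3 against 1085, 1597 and 1552 in the young libraries (adjusted p = 0.0718, and 0.0484 in edgeR). The count of rises was 19 without old 3, 5 without old 1, 1 without young 1 and 0 without young 2, without young 3 or without both young 1 and old 2, and the median was 0.62 without old 1. Of 21 chemokine and cytokine genes 7 rose (7 adjusted over the list alone; median 0.85, camera adjusted p = 0.00118; adjusted p = 0.597 with an estimated correlation), and 12 did so without old 3. Cxcl13, a B cell attractant, went from 1.76 ± 1.66 to 95.4 ± 39.5, Ccl6 from 32.1 ± 8.83 to 126 ± 23.4, and Il33 from 518 ± 77.8 to 933 ± 142.

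Markers of other leukocytes and blood were tested as cell types the nerve could hold. The lists of T and NK cells (6 genes), neutrophils (13) and erythroid cells (11) did not pass (camera adjusted p = 0.246, 0.239 and 0.239). No T or NK gene passed in limma or edgeR, and 3 of 6 were under 0.05 before adjustment in limma. Of the neutrophil genes Padi4 (1.47 ± 0.37) and Lcn2 (2.90 ± 0.80) rose, and none passed adjusted over the list alone. The adjusted p of Lcn2 was 0.0746 in edgeR, 0.0671 in the authors' own test and 0.0577 with the trends removed, and neither gene passed without young 2, old 1 or old 2. Of the erythroid genes only Sptb fell (-0.80 ± 0.13; with the trends removed -0.24, adjusted p = 0.101), and Hba-a2 stood at 1048 ± 305 and 3129 ± 1807 (adjusted p = 0.0612 in limma, 0.0450 in edgeR and 0.0256 in the authors' own test). Hbb-b1 (0.0323) and Hbb-bs (0.0322) passed in the authors' own test too. The neutrophil list passed without young 1 (adjusted p = 0.0129) and without old 2 (0.00753), the erythroid list without old 2 (1.96e-04) and the T and NK cell list without old 3 (0.0422). Without old 2 alone 9 of 14 erythroid genes rose (median 1.89), and without both young 1 and old 2 the rises were 9 of 13 neutrophil and 8 of 14 erythroid genes. Of 4 tested B and plasma cell genes Jchain, the joining chain of secreted antibodies, rose by a log2 fold change of 3.53 ± 0.76, to a mean of 182 ± 51.4 in old nerves, and did not pass without young 2 (adjusted p = 0.0536). Cd79b (-0.67), Mzb1 (-0.25) and Cd79a (0.13) did not pass, and the median of the 4 was -0.06 (0.26 without young 2 and 0.36 without old 1, with 5 genes tested).

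Genes of axonal excitability and the node of Ranvier fell. Of 25 tested, 22 fell and none rose (24 adjusted over the list alone; median log2 fold change -0.86, camera adjusted p = 4.12e-09; adjusted p = 0.597 with an estimated correlation). Hcn2, a hyperpolarisation-activated channel, fell from 7463 ± 238 to 2855 ± 1018. Cntnap1 (-1.22 ± 0.20), a paranodal adhesion protein, Ank3 (-0.96 ± 0.13), which anchors sodium channels, and Nfasc (-0.93 ± 0.13) fell too, whereas Scn1a (-0.43), Nrcam (-0.22) and Cntn1 (-0.09) did not pass. These transcripts are long, with a median of 6275 nt, and with the length and GC trends removed 18 fell and the median was -0.51. Without young 2, 12 fell, and without both young 1 and old 2, 7 fell.

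Synaptic vesicle genes fell in 18 of 25 cases with no rise (18 adjusted over the list alone; median -0.85, camera adjusted p = 1.18e-07; adjusted p = 0.597 with an estimated correlation). Pclo (piccolo), a scaffold of the active zone, fell from 4950 ± 605 to 2121 ± 298, the vesicle protein gene Syn1 from 8974 ± 551 to 3337 ± 1062, and the priming factor gene Unc13a by 1.34 on the log2 scale. Without young 2 or young 3 the count was 11, and without both young 1 and old 2 it was 6. Of 26 general neuronal genes 10 fell and none rose (10 adjusted over the list alone; median -0.50, camera adjusted p = 0.00110; adjusted p = 0.597 with an estimated correlation). Rbfox3 (NeuN) fell from 1858 ± 258 to 791 ± 256 and Elavl3 from 5247 ± 71.2 to 2749 ± 740, while Tubb3 (-0.23) and Snap25 (-0.35) did not pass. Without both young 1 and old 2, 1 of the 26 fell, and the median was -0.33 without young 1 and -0.32 without old 1. Markers of spiral ganglion subtypes were too few for the list test in types Ia, Ib and Ic. Pcdh20 (Ia) fell by 0.67 on the log2 scale, Ttn (Ib) by 1.38, Pou4f1 (Ic) by 1.26 and Grm8 (Ic) by 0.61, and Calb2, abundant in type Ia, was at 99299.5 ± 18433 and 97399 ± 13330.3 (log2 fold change -0.02). The Ttn transcript has 106824 nt, and with the trends removed its value was -0.64 (adjusted p = 0.0902). No type Ia or Ib gene fell without young 2, young 3, old 1 or old 2, and Grm8 passed in 1 of the 6 fits with 1 library left out, that without old 3. The type II list (7 genes, 1 higher and 2 lower, adjusted p = 0.977) had a median of 0.16 (-0.02 without young 2 and 0.27 with the trends removed) while fry's direction for it was down.

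Schwann cell myelin genes leaned lower, with 15 of 20 negative and 5 positive. Of 20 tested, 8 fell and 1 rose (8 and 1 adjusted over the list alone, median -0.17). The list did not pass (camera adjusted p = 0.0617), although it did without young 3 (0.0349). Fry passed it as lower (adjusted p = 0.0139). Cldn19, a tight junction protein of myelin, fell from 7540 ± 555 to 4249 ± 389. Egr2, the transcription factor that drives myelination, rose by 0.71 ± 0.10 and also stands in the immediate early list below. Pmp22 (0.11) and Mbp (0.44) did not pass, although Mbp was higher with the trends removed (0.60, adjusted p = 0.0474). The number that fell was 5 without young 2, young 3 or old 1 and 4 without both young 1 and old 2, and with the trends removed 6 fell and 2 rose. The median was -0.11 without young 1 or old 1. Prx fell by 0.59 on the log2 scale, and with the length and GC trends removed its value was -0.20 (adjusted p = 0.118).

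Astrocyte genes rose in 5 of 14 cases (5 adjusted over the list alone, median 0.24). The list passed in camera (adjusted p = 0.0280), but not with an estimated correlation (adjusted p = 0.597). Gfap also stands in the satellite and nonmyelinating glia list and Fgfr3 in the supporting epithelium list, so the list does not mark a single cell type. Gfap, an intermediate filament of reactive glia, rose from 12463 ± 3018 to 29016 ± 5315 and Aldh1l1 from 950 ± 132 to 1762 ± 91.8. The count was 3 and the list no longer passed without young 2 (adjusted p = 0.0527) or young 3 (0.0544). The median was 0.48 without young 1 and 0.59 without both young 1 and old 2. The oligodendrocyte list (15 genes, Aspa higher; adjusted p = 0.734), the satellite and nonmyelinating glia list (14 genes, 3 higher and 3 lower; 0.584) and the Schwann cell repair list (15 genes, 1 higher and 6 lower; 0.288) did not pass. Among them Apoe rose from 60038 ± 5729 to 122606 ± 21104 and Ngfr, the low-affinity neurotrophin receptor, fell from 7269 ± 76.5 to 3350 ± 884. With the trends removed no oligodendrocyte gene rose (Aspa was at 0.08) and Mog fell (-0.72, adjusted p = 0.0438). The falls of repair genes numbered 3 without young 2 or young 3 and 4 with the trends removed, and none rose without young 2 or old 2. Fry passed the repair list as lower (adjusted p = 0.026). The 24 cholesterol synthesis genes (1 higher, 5 lower; 0.274) included Srebf2, which fell by 0.55 on the log2 scale (with the trends removed -0.18, adjusted p = 0.109).

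Bone genes fell as a list, and matrix genes fell in part. The share of bone in each dissected sample was not measured here. Of 18 osteoblast and osteocyte genes 11 fell and none rose (13 lower and 1 higher adjusted over the list alone; median -1.12, camera adjusted p = 0.00118; adjusted p = 0.597 with an estimated correlation). Ibsp, a bone matrix protein, fell from 691 ± 150 to 267 ± 98.8 and Sp7 (osterix) from 501 ± 85.8 to 239 ± 76.1. The count of falls was 5 without young 1, 6 without young 2 or young 3, and 7 without old 1, and 1 gene rose without old 3. Of 34 extracellular matrix genes 13 fell and 3 rose (16 and 3 adjusted over the list alone; median -0.39, camera adjusted p = 0.00118; adjusted p = 0.610 with an estimated correlation). The basement membrane collagens Col4a1 (-0.96 ± 0.08) and Col4a2 (-0.74 ± 0.07; with the trends removed -0.19, adjusted p = 0.172) and the fibrillar Col5a2 (-1.02 ± 0.10) fell, and Postn, Lox (0.72) and Col8a1 (0.58) rose. With the length and GC trends removed 5 fell and 6 rose, the median was -0.16 and the list did not pass (adjusted p = 0.301). Its falls numbered 6 without young 1 or young 3, 7 without young 2, 8 without old 1 and 22 without old 2, and the median was -0.25 without old 3.

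Pericyte and smooth muscle genes fell in 3 of 13 cases (3 adjusted over the list alone; median -0.28, camera adjusted p = 0.0456; adjusted p = 0.597 with an estimated correlation). These were Notch3 (-1.06 ± 0.15), Pdgfrb (-0.62 ± 0.10; with the trends removed -0.33, adjusted p = 0.0638) and Myh11 (-1.04 ± 0.23). The list did not pass with the length and GC trends removed (0.222) or without young 1, young 2, old 1 or old 3 (adjusted p = 0.0734, 0.0851, 0.0699 and 0.0752), and its median was -0.43 without young 3. Endothelial (16 genes, 1 higher and 4 lower; adjusted p = 0.332), fibroblast (14, 3 and 3; 0.604), chondrocyte (12, 1 and 4; 0.176), osteoclast (6, 1 and 1; 0.734) and skeletal muscle genes (6, none; 0.734) did not pass as lists. No skeletal muscle gene was under 0.05 before adjustment in limma or passed in edgeR. Cldn5, an endothelial tight junction gene, fell by 0.61 on the log2 scale (adjusted p = 0.0617, 0.0504, 0.0682 and 0.0551 without young 1, young 2, young 3 and old 2), Ly6a rose from 166 ± 31.4 to 649 ± 270, and Cnmd rose from 4624 ± 1522 to 12661 ± 2103 while the other cartilage genes Col2a1 and Acan fell.

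Cochlear supporting epithelium genes rose in 5 of 12 cases (5 higher and 1 lower adjusted over the list alone; median 0.59, camera adjusted p = 0.0363; adjusted p = 0.648 with an estimated correlation). The share of cochlear epithelium in each dissected sample was not measured here. Epyc went from 7053 ± 2484 to 17795 ± 6479, Fbxo2 from 15209 ± 3551 to 31837 ± 9672, and the anion exchanger gene Slc26a4 (pendrin) from 1901 ± 559 to 4125 ± 1515. The list did not pass without young 1 (adjusted p = 0.121) or old 1 (0.0863), where 3 rose, as without both young 1 and old 2, and 1 rose without young 2. Its median was 0.25 without young 1, 0.37 without old 1, 0.91 without young 3 and 0.89 with the trends removed. The hair cell list (17 genes, Cdh23 lower; adjusted p = 0.959) had a median of 0.08 (-0.28 to 0.37 with 1 library left out) and a mean of -0.02, and with the trends removed Cdh23 was at -0.35 (adjusted p = 0.219). The stria vascularis list (13 genes, 2 higher and 1 lower; adjusted p = 0.0773) passed without young 2 (0.0253), without old 2 (0.0170) and with the trends removed (0.0291). Its potassium channel gene Kcnq1 rose from 114 ± 27.8 to 297 ± 64.6. The choroid plexus and meninges list (11 genes, 3 higher; 0.121) passed without old 3 (0.0362), and its members Ttr and Otx2 (165 ± 67.0 to 808 ± 303) rose. Brainstem neuron genes did not pass (10, 1 and 1; 0.656), with Cbln1 higher by 1.26 ± 0.14 and Reln lower by a log2 fold change of -1.02 ± 0.12.

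Ribosomal protein genes rose in 42 of 47 cases with no fall (43 adjusted over the list alone; median 0.64, camera adjusted p = 1.94e-16; adjusted p = 0.597 with an estimated correlation). Rps14 rose from 2420 ± 71.8 to 4197 ± 381 and Rpl32 from 2352 ± 130.0 to 3911 ± 272. These transcripts are short, with a median of 975 nt, and with the trends removed 11 rose and the median was 0.27. Nuclear-encoded oxidative phosphorylation genes, median 1187 nt, rose in 19 of 40 cases with 1 fall (22 and 1 adjusted over the list alone; median 0.22, camera adjusted p = 1.92e-04; adjusted p = 0.597 with an estimated correlation). Ndufa2 rose by 0.40 ± 0.07 and Cox8a by 0.46 ± 0.09. With the trends removed the direction turned, with a median of -0.15, 6 falls and no rise (adjusted p = 0.00164). The rises numbered 7 without young 1 or old 2, 4 without young 2, 8 without young 3 and 0 without both young 1 and old 2, and 3 fell without old 3. Mitochondrially encoded genes were not analysed here.

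Antioxidant genes rose in 12 of 24 cases and fell in 4 (13 and 4 adjusted over the list alone; median 0.27, camera adjusted p = 0.00338; adjusted p = 0.597 with an estimated correlation). Mt2, a metallothionein with a mean of 10184 ± 2216 in old nerves, rose by 2.05 ± 0.16, Mt1 by 1.55 ± 0.14, and the peroxiredoxin gene Prdx6 by 0.97 ± 0.11. With the trends removed 7 rose and 3 fell, the median was 0.08 and the list did not pass (adjusted p = 0.144). Its falls numbered 1 without young 2, young 3 or old 2 and 2 without young 1 or old 1, and without both young 1 and old 2, 6 rose and none fell. Of 26 lysosome genes 14 rose and 2 fell (15 and 4 adjusted over the list alone; median 0.26, camera adjusted p = 0.00155; adjusted p = 0.597 with an estimated correlation). Gpnmb, a lysosomal glycoprotein of phagocytes, went from 55.4 ± 19.1 to 1401 ± 780. The lysosome count was 6 higher and 1 lower without both young 1 and old 2 and 15 and 5 without old 3, and 1 fell without young 2, young 3, old 1 or old 2. Of 18 immediate early genes 8 rose and none fell (9 adjusted over the list alone; median 0.49, camera adjusted p = 0.00412; adjusted p = 0.597 with an estimated correlation). Nr4a1 (1.31 ± 0.26), Btg2 (1.02 ± 0.14) and Zfp36 (0.88 ± 0.14) were among them, and the count was 5 without young 1, young 2, old 2 or both young 1 and old 2 and 4 without young 3. Their median was 0.26 without old 2, 0.30 without young 2 and 0.77 without old 1.

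The heat shock list (23 genes, 5 higher and 2 lower; adjusted p = 0.0773), the senescence and secretory phenotype list (13 genes, 3 higher; 0.110) and the cell cycle list (27 genes, 3 higher; 0.235) did not pass. Heat shock genes passed without young 3 (0.0374), old 1 (0.0499) or old 3 (0.0295), and senescence genes without young 1 (0.0418), young 3 (0.0271) or old 3 (0.0353). Fry passed the senescence list as higher (adjusted p = 0.0442). With the trends removed 2 heat shock genes were higher and 3 lower. Cryab rose by 0.62 ± 0.10 and Bag3 fell by 0.65 on the log2 scale. Plaur, the urokinase receptor, rose from 8.38 ± 3.91 to 68.3 ± 7.85, and the DNA-binding protein gene Hmgb2 from 77.7 ± 5.25 to 246 ± 55.6. Adjusted over the list alone, the lists that did not pass gave the counts above except for these. Satellite glia genes had 4 higher and 4 lower, repair genes 2 and 6, cholesterol genes 1 and 4, stria genes 2 and 0, heat shock genes 4 and 2, cell cycle genes 2 and 0 and type Ic genes 0 and 4, while no oligodendrocyte, hair cell or neutrophil gene passed. With 1 library left out, the count of rises or of falls moved by over 1.5 times in at least 1 fit for every list that did not pass, apart from skeletal muscle. With the trends removed the counts were 1 higher and 1 lower for type II genes, 1 and 2 for chondrocytes, 0 and 2 for endothelial cells, 1 and 3 for fibroblasts, 1 and 0 for osteoclasts, 1 and 0 for neutrophils, 1 and 0 for T and NK cells, 0 and 1 for skeletal muscle, 2 and 0 for the stria, 2 and 1 for brainstem neurons and 3 and 1 for senescence.

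**Figure D3:**
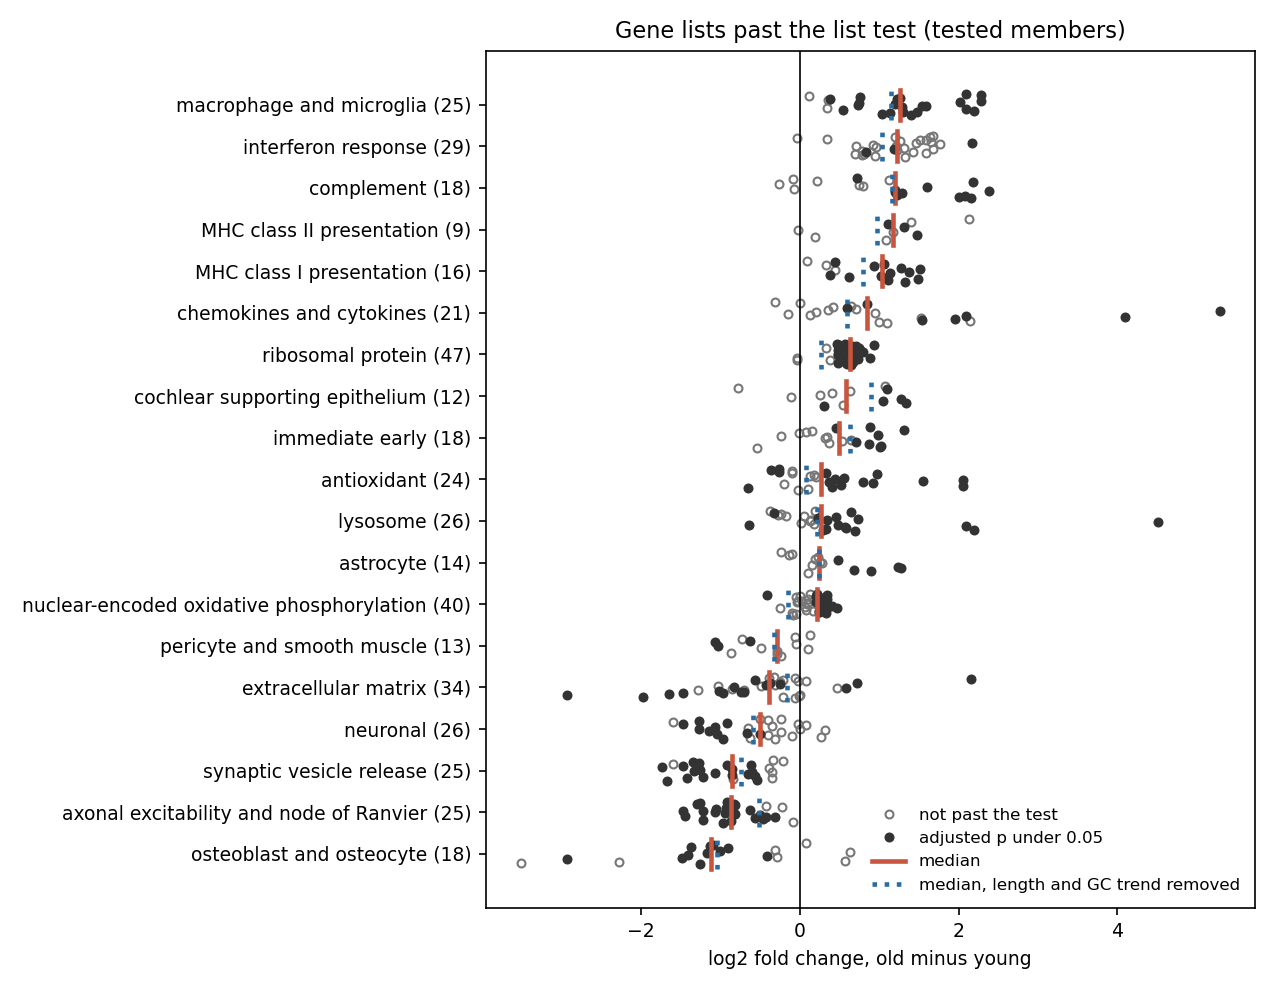
Log2 fold change (old minus young) of each tested member of the 19 gene lists past the list test, with the number of tested members in parentheses. Filled points have an adjusted p under 0.05, solid bars are list medians and dotted bars are medians with the length and GC trends removed. Macrophage genes have a median of 1.26 and axonal excitability genes one of -0.86, and the oxidative phosphorylation median turns from 0.22 to -0.15.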

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

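Tests with the length and GC trends removed, without young 1 and old 2, with TMM scaling in edgeR and in limma, with fry and with the authors' own FDR were chosen only after the results were seen, and the others were set before the data were examined. The count of 5493 genes stayed between 5265 and 6137 with DESeq2, edgeR under 3 scalings, other filters, pseudocounts and scalings in limma, and the authors' own FDR. None of these turned the direction of a shared call. The count was 948 with at least a 2-fold change and 1866 at an adjusted p under 0.01, which are stricter by construction. With the length and GC trends removed it was 3505 (1589 higher, 1916 lower), of which 2752 were shared in direction with the calls above and 11 were opposite. Leaving out 1 library gave 2589 to 6117 genes. The lowest counts were 2589 without young 2, 3077 without young 3 and 3565 without young 1, with fewer samples in each. Without young 1 and old 2 it was 1776, from 4 libraries.

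The labels do not say whether the replicate numbers pair the samples. The correlations of deviations between young and old libraries of the same number were -0.291, -0.412 and -0.0499, and no library correlated best with its own number. By the sample numbers in the column names, the order was young 1, old 1, young 2, old 2, young 3, old 3. A step shared by libraries of the same number therefore cannot be excluded. With the replicate block 2711 genes passed (1078 higher, 1633 lower) and 19 lists, as without it.

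Of 40 lists, 19 passed (13 up, 6 down). With an estimated correlation 0 passed, with a smallest adjusted p of 0.597, and only the antioxidant list was under 0.05 before adjustment. Camera's estimate from 6 libraries was often high, as with 0.540 for macrophage genes. With fry 12 passed (8 up, 4 down), 9 of them shared. Fry added the Schwann cell myelin, repair and senescence lists. It did not pass the oxidative phosphorylation, osteoblast, extracellular matrix, astrocyte and pericyte lists (fry adjusted p = 0.0545 to 0.0802). Nor did it pass the immediate early, neuronal, class II, supporting epithelium and interferon lists (0.0819 to 0.221). Leaving out 1 library gave 18 to 22, and 17 passed with the trends removed. With the genes that stand in several lists left out, 18 passed (11 up, 7 down), 17 of them shared. The oxidative phosphorylation list turned to a median of -0.15 with the trends removed, as did Ndufa2 (-0.0492) and Ndufv2 (-0.0914). These transcripts are short, which is what the removal acts on. Among 181 named genes, 141 of them called, 4296 values under alternatives gave 3933 on the same side of the threshold, 312 that lost the call, 49 that gained it and the 2 reversals above. All alternatives ran except those that needed a table of the authors' p-values alone. Depth limits genes with few reads. Of simulated changes, 36 of 103 were recovered in genes with a mean below the median and 80 of 97 in the others.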

Other observations

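The tests of length and GC, of cell shares and of sample splits were chosen only after the results were seen, and the tests of glucocorticoid-inducible and imprinted genes were written down before those genes' values were looked at. The random lists used below drew each gene singly, so their ranges leave out correlation between genes and spread between mice. The genes in the next paragraph were picked after their values were seen.

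Cst7, a cystatin of activated microglia, had a mean of 2.67 ± 1.10 normalised reads in the young libraries and 309, 378 and 175 in the old ones (log2 fold change 6.26 ± 0.38, limma adjusted p = 0.00231). Itgax (CD11c) went from 10.6 ± 8.36 to 298 ± 83.5, Clec7a (dectin-1) from 97.1 ± 15.6 to 517 ± 114 and Lpl (lipoprotein lipase) from 229 ± 17.0 to 1063 ± 367. Atp6v0d2, a proton pump subunit of osteoclasts and macrophages, went from 2.90 ± 2.41 to 95.9 ± 52.7, and its osteoclast list did not pass. Srd5a2, a steroid 5-alpha-reductase, was at 0 in all 3 young libraries and at 63.4, 56.0 and 24.2 in the old ones, at least 47.5-fold higher against a floor of 3 reads over the group. Pdyn, the precursor of dynorphin peptides, went from 10.7 ± 8.66 to 156 ± 83.5. Rn45s, a ribosomal RNA precursor, stood at 152889 in young 3 and between 19552 and 44951 in the other libraries.

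Young 1 and old 2 shared deviations from their groups (correlation across genes 0.396). Both were high in Chrnb3, a nicotinic receptor subunit (1608, 21.6 and 268 in the young libraries, 2.11, 565 and 0.967 in the old ones), and in Kcnc2, Syt1 and Pcp4. Both were low in Crhbp, Cndp1 and Scnn1a. No explanation of this was tested.

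The rise of macrophage genes was weighed first. Random lists matched on level, length and GC had medians in a central 95% range from -0.07 to 0.28, and the list's 1.26 was at percentile 100, which argues against the length and GC trend as its whole cause. A larger share of macrophages in an unchanged state would raise all members alike, but with the trends removed they ran from 0.05 (P2ry12) to 2.31 (Mpeg1), a heterogeneity ratio of 13.4 against a bound of 2.60. A mixed account may hold, with more macrophages that are also in another state, or different kinds of macrophage. Age itself stays open as the origin.

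The medians of the excitability and synaptic genes, -0.86 and -0.85, were at percentiles 0 and 0 of matched random lists, below ranges from -0.48 to -0.14 and from -0.35 to -0.02, so the length and GC trend does not account for all of either. A lower share of all neurons alike would move 39 neuron-restricted genes by a common amount. They were picked after their values were seen and include Sv2c and Bsn, among the largest falls, and Tubb3 and Snap25, which did not pass. A ratio above the bound could therefore be foreseen and does not decide the question. As measured the heterogeneity ratio was 8.08 against a bound of 2.37, with Sncg at 0.07, Stmn2 at -0.02 and Pvalb at 19052 ± 1283 and 19063 ± 2036. After removal of the trends it was 4.55 against 2.36 and all 39 were negative, from -0.11 (Nefh) to -1.42 (Sv2c) and -1.53 (Syt1, adjusted p = 0.351), with Sncg at -0.22, Stmn2 at -0.27 and Pvalb at -0.44 (adjusted p = 0.0343). A partial loss of neurons, unequal loss of neuron types, lower expression per neuron or a remaining trend stay open.

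Ribosomal protein and oxidative phosphorylation genes, both short, parted under the same test. The ribosomal median of 0.64 was at percentile 100 of matched random lists (range 0.17 to 0.34), so the trend could account for part of it only. The oxidative phosphorylation median of 0.22 was at percentile 21.9 (range 0.17 to 0.34), no higher than in genes matched on level, length and GC. Ribosomal protein genes were not kept out of those matched genes, so the test does not show that the trend accounts for all of it. RNA quality may differ with age in a way that gives such a trend, but no measure of it was used here, and an effect of age on long transcripts cannot be excluded. The falling excitability and synaptic lists are long too (medians 6275 and 4412 nt). The removal may therefore also take away part of a change that has another origin.

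Of the 10 splits of the 6 libraries into 3 and 3, only the real one, 1 split, gave as many as 5493 genes, and the highest of the others gave 0. There are too few splits for a share under 0.05.

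A first hypothesis came from Mt2, Sgk1 and Cebpd, genes that glucocorticoids induce, which rose by 2.05, 1.69 and 1.87. If the old nerves were under more glucocorticoid signalling, 12 other inducible genes should be higher. Their median was 0.79, at percentile 100 of matched random lists (range -0.29 to 0.16), and 11 of 12 rose, among them Per1 (2614 ± 1084 to 7043 ± 501), Ddit4 (1.49 ± 0.21), Fkbp5 (0.81 ± 0.23) and Tsc22d3 (0.77 ± 0.21), the exception being Zbtb16 (-0.27). The percentile covers spread across genes drawn singly, and leaves out that these genes move together and that mice differ. After removal of the trends 9 rose, without Tsc22d3 (0.54, limma adjusted p = 0.129) and Sult1a1 (0.32, 0.183). Old 2 was the lowest old library in 11 of the 12 and young 2 the highest young one in 11, and in Fkbp5, Tsc22d3, Hif3a and Klf9 old 2 (1900, 8914, 204.0 and 3595) lay close to young 2 (1779, 8772, 203 and 3703). The result is consistent with more glucocorticoid signalling, but Per1 also follows the time of day and several of these genes answer to other stress, and times of collection were not used here.

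A second hypothesis was that collagen and bone matrix genes fell because growth was still under way at the young age. An imprinted growth network of 10 genes should then be lower, beyond matched lists. Its median of -0.33 (-0.07 with the trends removed) was at percentile 5.39, inside the range from -0.38 to 0.12, so the prediction was not met. Of the 10 genes 8 were negative, and Mest (-0.74), Ndn (-0.50) and Igf2r (-0.28; with the trends removed 0.08, adjusted p = 0.436) fell, while none rose and Igf2 was at 16546 ± 5005 and 18718 ± 7990.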
